A study of Homo sapiens with 12 samples.

How the data were processed

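RNA had been sequenced from 12 libraries of A498 cells, with 3 biological replicates of each of 4 siRNA treatments, on a NextSeq 500 as paired-end 36-base reads, per the labels. The deposited table gives 1 normalized signal value per gene and library for 57773 genes, and the authors' label for it is normalized. The aligner, the counting tool, the annotation and the genome build are not given in the sources used here, so genes are named by the symbols of the table and no coordinates are given. The values themselves show the step that the authors applied. Every column holds an identical set of values, and each value is a multiple of 1 over 12, which is what quantile normalization of read counts over 12 libraries gives. The total of every column is therefore 8.525 M, the highest value is 61280, and each column holds 39839 values of 0 (69.0%). These are not the same genes in every column, and 34041 genes stand at 0 in all libraries. Whole reads could be recovered only for low counts, so the count-based test that had been planned for recoverable reads was not run. A total of 2234 genes carry a numbered suffix in their name. They were kept as separate genes, and whether they are different loci with the same symbol was not examined.

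Sequencing depth was recovered from the order of tied values. Genes with the same low count in a library had received successive normalized values in table order, so each break in that order marks a step of 1 read. The median ratio of read count to normalized value over counts from 20 to 60, multiplied by the column total, gave an estimated depth. Tested on simulated data for 57773 genes, the procedure recovered 100% of the counts up to 60 and gave depths between 1.002 and 1.02 times the true ones. The simulated libraries shared 1 set of gene means and were scaled by depth only. In the deposited data the ratio of reads to normalized value at 100 reads was 0.798 (siELOVL5 replicate 3) to 1.052 (siELOVL2 replicate 1) of that at 10 reads. The estimated depths are therefore less certain than in the simulation. Exact binomial intervals given in the text cover counting error only.

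Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3. Genes with a value of at least 1 in at least 3 of the 12 libraries were tested, which left 18648. All 4 groups were fitted together with group means and no further terms, which leaves 8 residual degrees of freedom, and variances were moderated with an intensity trend. Each knockdown was compared with the control siRNA, the knockdowns were compared with each other, and an interaction (double knockdown minus siELOVL2 minus siELOVL5 plus control) was tested. Benjamini-Hochberg adjustment was applied within each comparison, with a threshold of 0.05, and fold changes are given on the log2(value + 1) scale with their standard errors (SE). A gene is called when its adjusted p lies under that threshold.

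Gene lists were tested with camera from limma, with its preset correlation between genes of 0.01, and again with the correlation estimated from the data, which is the stricter test. There were 31 lists with 838 genes. They covered fatty acid elongation and desaturation, cholesterol biosynthesis and uptake, de novo fatty acid synthesis, fatty acid oxidation and PPAR targets, lipid droplets and triglyceride storage, phospholipid remodelling, eicosanoid synthesis, the unfolded protein response, ATF4 and amino acid response genes, NRF2 and ferroptosis genes and hypoxia-inducible factor targets. They also covered interferon-stimulated genes, NF-kappaB and inflammatory cytokines, STAT3 targets, FOXO and PI3K-AKT feedback, apoptosis regulators, p53 targets, DNA replication and G1/S, mitosis and G2/M, epithelial and proximal tubule markers, mesenchymal and matrix genes, TGF-beta early targets and immediate early genes. The others were nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, cytosolic ribosomal proteins, replication-dependent histones, RNA interference machinery, leukocyte markers, endothelial markers, and fibroblast and pericyte markers. Of the 838 genes, 783 were found under the same name, 35 through an older name in GENCODE 29, 14 through a RefSeq synonym, and 6 had no match. Reads shared between near-identical copies could not be told apart, so values of histone genes, ribosomal protein genes, mitochondrial transcripts and HMGB3 are uncertain.

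The comparisons, tests, lists and most alternatives were fixed before the data were examined, as was the rule for naming genes. ELOVL2 and ELOVL5 were always named. For each knockdown against control, the rule took up to 10 genes in each direction with the largest fold changes. They had to be called, to have all 3 knockdown libraries on the same side of all 3 controls, and to have a mean level at or above the median of tested genes (93.8). For the differences between knockdowns and the interaction it took up to 5 each way. For each list it took up to 4 called members with the smallest p, or up to 2 uncalled ones as values.

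The labels number the replicates 1 to 3 in every group but state no shared day or batch. Whether same-numbered libraries vary together was therefore checked from their deviations from the group means, as correlations across genes. For siELOVL2 against control these were 0.681, 0.109 and 0.636, for siELOVL5 against control 0.439, 0.161 and 0.221, and for siELOVL5 against siELOVL2 0.429, 0.227 and 0.187. All of these lie over 0.1, so for these comparisons a fit with replicate number as a block is given beside the result where it changes a call or moves a count by over 1.5 times. For the double knockdown the correlations were 0.608, 0.0845 and 0.654 against control and 0.724, 0.053 and 0.753 against siELOVL2. Against siELOVL5 they were 0.369, 0.0721 and 0.201. With number 2 under 0.1 these comparisons did not meet that criterion, although numbers 1 and 3 lay over it. Of the 12 libraries, 11 had their highest mean correlation with libraries of their own number. Counts with the block are therefore given for these comparisons too where they move by over 1.5 times.

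The fit was tested on simulated data in which 200 of 18648 genes were changed by known amounts. For siELOVL2 against control it recovered 55.2%, 92.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale. For siELOVL5 against control it recovered 44.8%, 89.6% and 100%, and for the double knockdown 52.2%, 95.5% and 100%. For the interaction it recovered 7.46%, 70.1% and 100%. False calls numbered 6, 8, 13 and 4 in these simulations. In the deposited data the median SE over the tested genes was 0.210 for comparisons of 2 groups and 0.297 for the interaction. The recovery holds for the simulated genes and is lower for genes with a larger SE.

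Alternatives covered a pseudocount of 0.1, no filter, a stricter filter at 5, quantile normalization of the log2 values, TMM scaling, limma without the intensity trend, the replicate block, fits on the groups compared alone, and leaving out each library in turn. Library weights, regression on transcript length and GC content with and without the block, and comparisons that share no library were added after seeing the data. For the comparison of knockdowns with the same controls, 100 simulated sets of unchanged groups gave the values expected from sharing controls. To look for siRNA seed sites, 16138 words of 7 bases were scanned in 3′ untranslated regions (UTRs) from GENCODE 29. The 9050 genes scanned had a mean level at or above the median of tested genes. The fold changes of carriers and other genes, with extremes clipped, were compared after adjustment for UTR length and GC content. The test was Bonferroni-adjusted and treats genes as independent, which they are not. The sequences of the siRNAs are not given in the sources used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.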

Results

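Transcript levels were measured by RNA sequencing in 12 libraries of A498, a human kidney carcinoma cell line. The cells had received a control siRNA, an siRNA against ELOVL2, an siRNA against ELOVL5, or both siRNAs, with 3 biological replicates in each of the 4 groups. An siRNA is a short RNA duplex that lowers the transcript it matches, and ELOVL2 and ELOVL5 are enzymes that lengthen polyunsaturated fatty acids. The deposited values are read counts after the authors' quantile normalization, called normalized counts here, and they total 8.525 M in every library. The depth before that step was estimated from ties among low counts. It was 6.80, 8.31 and 8.97 M reads in control replicates 1, 2 and 3, and 9.58, 9.18 and 9.14 M in the siELOVL2 replicates. It was 9.36, 10.8 and 7.85 M in the siELOVL5 replicates and 6.79, 7.82 and 8.88 M in the double-knockdown replicates. A gene with no read could still hold a normalized count of up to 0.917, in control replicate 1, so differences below that level were not detectable.

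Both siRNAs lowered their targets in every library that received them. ELOVL2 stood at 269.9 ± 50.7 normalized counts (SD, n = 3) in control cells, 25.2 ± 6.05 in siELOVL2 cells and 23.9 ± 3.53 in double-knockdown cells, which is 9.32% and 8.87% of control. ELOVL5 stood at 1977 ± 53.2 in control cells, 148 ± 7.43 in siELOVL5 cells and 179 ± 7.50 in double-knockdown cells, or 7.48% and 9.03% of control. ELOVL2 fell by 3.38 on the log2 scale with its own siRNA (SE 0.24, limma adjusted p = 1.61e-05) and by 3.43 with both siRNAs (adjusted p = 8.97e-06). ELOVL5 fell by 3.73 with its own siRNA (SE 0.09, limma adjusted p = 1.36e-10) and by 3.46 with both (adjusted p = 3.53e-10). Neither target changed with the other siRNA past the threshold. ELOVL2 was at 228 ± 60.8 in siELOVL5 cells (log2 fold change -0.26, limma adjusted p = 0.765) and ELOVL5 was at 2038 ± 271 in siELOVL2 cells (0.04, adjusted p = 0.919).

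**Figure D1:**
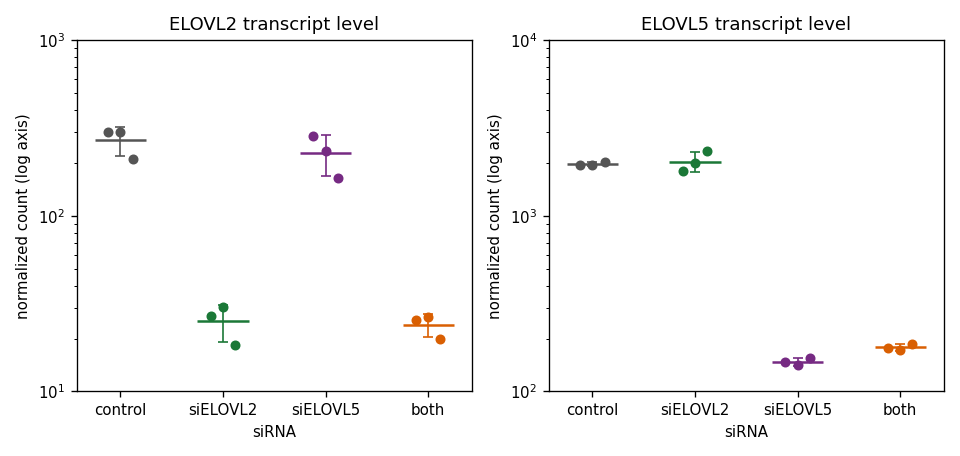
Normalized counts of ELOVL2 (left) and ELOVL5 (right) on log axes, by siRNA; points are the 3 biological replicates of each group, lines the mean and bars the SD. ELOVL2 lies between 18.4 and 30.1 in the 6 libraries that received its siRNA and at 164.6 or above elsewhere, and ELOVL5 lies between 140.8 and 186.8 in the 6 that received its own and at 1791 or above elsewhere.

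The first comparison asks what lowering ELOVL2 does to expression. The largest rise was that of HMOX1, the heme oxygenase that degrades heme, from 2820 ± 421 normalized counts (SD, n = 3) in control cells to 15730 ± 2542 in siELOVL2 cells (log2 fold change 2.48, SE 0.21, limma adjusted p = 9.52e-05). SLC48A1, a heme transporter, rose from 324 ± 34.0 to 617 ± 62.0 (0.93, adjusted p = 7.92e-04), and POR, the reductase that supplies electrons to cytochrome P450 enzymes and heme oxygenase, rose from 1819 ± 147 to 3219 ± 295 (0.82, adjusted p = 0.00123). ZNF469, a zinc finger protein gene, rose by 1.24, the ER peptidase gene ERMP1 by 0.85 and the lysosomal sialidase gene NEU1 by 0.79. FBXO32, a ubiquitin ligase subunit gene, was called at 1.06, the glycosyltransferase gene GALNT9 at 0.92, the cell cycle factor E2F5 at 0.81 and INSR, the insulin receptor, at 0.77. Among the falls other than ELOVL2, CCNG1, which encodes cyclin G1, went from 686 ± 41.3 to 228 ± 32.3 (-1.59, limma adjusted p = 9.83e-06), and DUSP3, a protein phosphatase gene, went from 1442 ± 130.5 to 512 ± 55.8 (-1.49, adjusted p = 9.83e-06). The ceramide kinase CERK went from 365 ± 28.4 to 131 ± 14.4 (-1.48), the galactosyltransferase B4GALT1 from 4202 ± 108 to 1662 ± 83.2 (-1.34), and VBP1, a prefoldin subunit, from 610.4 ± 23.3 to 229 ± 35.1 (-1.42). HMGB3, MOB1A and PEG10 fell by 1.60, 1.34 and 1.27 on the log2 scale; HMGB3 is uncertain because many pseudogenes resemble it. Of the 9 named falls other than ELOVL2, 7 carry in the 3′ UTR at least 1 of 3 related 7-base words that marked falling transcripts (ACGAATA, CACGATA and ACGATAA, chosen after a scan of all words). CCNG1, DUSP3, CERK, VBP1, MOB1A, PEG10 and ZNF367 are the carriers and B4GALT1 and HMGB3 are not, and 0 of the 10 named rises carry one.

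In all, 254 of 18648 genes were called, 102 higher and 152 lower, and 9 of the rises and 26 of the falls were at least 2-fold. With replicate number as a block the count was 861, and these included all 254. The fits without 1 library, here and below, had no block, so differences between replicate numbers were not taken out of them. The count moved by over 1.5 times when 1 library was left out: to 65, 63 and 144 without control replicate 1, 2 or 3, to 95, 71 and 83 without siELOVL2 replicate 1, 2 or 3, and to 829 without siELOVL5 replicate 3. It was 101 in limma without the intensity trend, 412 in a fit on these groups alone and 1569 with library weights. The other genes named above stayed called without any 1 library, but 5 did not. ZNF367 (-1.40) was lost without control replicate 1 (0.0783) or 2 (0.0675) or siELOVL2 replicate 2 (0.0673) or 3 (0.0641). FBXO32 was lost without control replicate 1 (0.115), 2 (0.123) or 3 (0.0892), siELOVL2 replicate 1 (0.115), 2 (0.0922) or 3 (0.0788) or double-knockdown replicate 2 (0.0509). GALNT9 was lost without control replicate 1 (0.170) or 2 (0.177), siELOVL2 replicate 1 (0.0561), 2 (0.107) or 3 (0.146), siELOVL5 replicate 1 (0.0502) or 2 (0.0588) or double-knockdown replicate 1 (0.0584) or 2 (0.0561). E2F5 was lost without control replicate 1 (0.0828) or 2 (0.0861) or siELOVL2 replicate 1 (0.0587), 2 (0.0583) or 3 (0.0888), and INSR without control replicate 1 (0.0970) or 2 (0.0680) or siELOVL2 replicate 1 (0.0566), 2 (0.0912) or 3 (0.0819).

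Genes of the antioxidant factor NRF2 and of ferroptosis shifted upward after siELOVL2. Of 31 measured, 29 lay above control with a median of 0.31 (camera adjusted p = 2.11e-11), 4 were called higher (14 with the replicate block, and 8 without siELOVL5 replicate 3), and 16 were higher when adjusted over the list alone. With an estimated correlation the adjusted p was 0.0637, and with the replicate block as well it was 0.0435. Beside HMOX1, GCLM, a subunit of the enzyme that limits glutathione synthesis, rose by 0.75 (limma adjusted p = 0.00103). The quinone reductase NQO1 was called at 0.47 and the lipid peroxidase GPX4 at 0.39. NQO1 was lost without control replicate 1 (0.0860) or 2 (0.112) or siELOVL2 replicate 1 (0.0539), 2 (0.0602) or 3 (0.0896), and GPX4 without control replicate 1 (0.0695), 2 (0.177) or 3 (0.138), siELOVL2 replicate 1 (0.147), 2 (0.128) or 3 (0.0821), siELOVL5 replicate 2 (0.0634) or double-knockdown replicate 1 (0.0614) or 2 (0.0718). BACH1, which represses HMOX1 and carries CACGATA in its 3′ UTR, had a log2 fold change of -0.68 (limma adjusted p = 0.178, and 0.0337 with the block). It was chosen after its values were seen. The NRF2 gene NFE2L2 and its repressor KEAP1 were at 0.05 and 0.07 (adjusted p = 0.925 and 0.731).

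Cell cycle lists shifted downward as sets after siELOVL2. Mitosis and G2/M genes had a median of -0.42 with 38 of 40 below control (camera adjusted p = 1.75e-07, and 0.838 with an estimated correlation). Histone genes were at -0.32 with 27 of 28 below (7.55e-08, and 0.793), and DNA replication and G1/S genes at -0.24 with 36 of 40 below (2.09e-07, and 0.838). Limma called 0 histone and 0 G2/M genes, over all genes or adjusted over the list alone, and 9 and 6 had an unadjusted p under 0.05. With the replicate block 5 of each were called lower, and 1 G1/S gene. Without siELOVL5 replicate 3, a library outside this comparison, 7 histone, 4 G2/M and 15 G1/S genes were called lower. With all libraries and no block the 1 call in the G1/S list was CCNE1, cyclin E1, which went up by 0.50 against the direction of its list (adjusted p = 0.0290). It was lost without control replicate 1 (0.137) or 2 (0.139), siELOVL2 replicate 1 (0.0882), 2 (0.0686) or 3 (0.133) or double-knockdown replicate 2 (0.0509).

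Mesenchymal and matrix genes were at a median of -0.16 after siELOVL2 with 26 of 34 below control (camera adjusted p = 2.02e-05, and 0.0637 with an estimated correlation); 3 were called lower (10 with the block, and 7 without siELOVL5 replicate 3), and 8 when adjusted over the list alone. CDH2, the adhesion protein N-cadherin, fell from 2884 ± 139 to 1734 ± 69.5 (SD, n = 3; -0.73, limma adjusted p = 4.19e-04), and its 3′ UTR carries ACGATAA. Targets of hypoxia-inducible factor had a median of -0.15 with 22 of 31 below (camera adjusted p = 7.82e-04, and 0.793 with an estimated correlation). EGLN1, a prolyl hydroxylase that modifies that factor, fell by 0.62 on the log2 scale (limma adjusted p = 0.00149) and carries ACGAATA. The growth factor TGFA (-0.70) and the lactate dehydrogenase LDHA (-0.35) were also called. TGFA was lost without control replicate 1 (0.134) or 2 (0.131) or siELOVL2 replicate 1 (0.0887), 2 (0.0632) or 3 (0.126), and LDHA without control replicate 1 (0.113), 2 (0.165) or 3 (0.0935), siELOVL2 replicate 1 (0.110), 2 (0.125) or 3 (0.109) or double-knockdown replicate 2 (0.0543). The p53 target list was at 0.18 with 29 of 33 above (0.00138, and 0.793), while its only called member, CCNG1, fell (with the block 2 others were called higher); the list lost its call without control replicate 3 (0.0665) or siELOVL2 replicate 1 (0.0677).

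A further 3 lists passed the preset test after siELOVL2 with small shifts. Nuclear-encoded oxidative phosphorylation genes were at 0.09 (camera adjusted p = 0.00735, and 0.839 with an estimated correlation), which was lost without control replicate 2 (0.0671) or siELOVL2 replicate 3 (0.0908). TGF-beta early targets were at -0.07 (0.0460, and 0.270), lost without control replicate 1 (0.158) or 2 (0.0598), siELOVL2 replicate 1 (0.0677) or 3 (0.0656) or double-knockdown replicate 1 (0.0564) or 3 (0.0517), without the trend (0.0729) and with library weights (0.0553). PMEPA1, an inhibitor of TGF-beta signalling, and SKIL, a repressor of SMAD proteins that carries ACGATAA, were called lower (-0.56 and -0.40). PMEPA1 was lost without control replicate 1 (0.104) or 2 (0.121) or siELOVL2 replicate 1 (0.0806), 2 (0.0531) or 3 (0.108), and SKIL without control replicate 1 (0.131), 2 (0.139) or 3 (0.0645) or siELOVL2 replicate 1 (0.10), 2 (0.126) or 3 (0.0960). Fatty acid oxidation and PPAR targets were at 0.09 (0.0482, and 0.838), lost without control replicate 1 (0.169) or 2 (0.116), siELOVL2 replicate 2 (0.0699) or 3 (0.469), siELOVL5 replicate 2 (0.0505) or 3 (0.0531) or double-knockdown replicate 1 (0.0564) or 2 (0.0525), with quantile normalization (0.0505) or TMM scaling (0.0559) and without the trend (0.0729). Limma called 0 of its genes, 5 had an unadjusted p under 0.05, and with the block 4 were called higher. De novo fatty acid synthesis genes had a median of 0.26 that missed the threshold (0.0979) but passed with the block (0.00162, and 0.372 with an estimated correlation), where 3 were called higher. Interferon-stimulated genes were at -0.12 (0.113, and 0.0296 with the block, where an estimated correlation gave 0.853).

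The second comparison asks what lowering ELOVL5 does. Beside ELOVL5, the falls included UBE2E3, a ubiquitin-conjugating enzyme gene, from 516 ± 44.5 normalized counts (SD, n = 3) in control cells to 228 ± 19.6 in siELOVL5 cells (log2 fold change -1.17, SE 0.13, limma adjusted p = 0.00131). FBXL16, an F-box protein gene, went from 230 ± 8.70 to 103 ± 12.6 (-1.16, adjusted p = 0.00351). LEPROTL1, related to the leptin receptor overlapping transcript, went from 409 ± 22.1 to 210.0 ± 6.68 (-0.96, adjusted p = 1.78e-04), and EIF4EBP2, which restrains cap-dependent translation, from 1366 ± 51.6 to 784 ± 44.0 (-0.80, adjusted p = 5.60e-04). Limma also called the heat shock gene HSPA2 (-1.09), COMMD8 (-1.09), FAM105A (-0.88), ZNF618 (-0.86) and SMAP2 (-0.81) lower. It called CPA4, a carboxypeptidase gene, 0.90 higher, the organic anion transporter SLCO2B1 0.62 higher and RAPGEF2 0.43 higher. Of the 9 named falls other than ELOVL5, 6 carry in the 3′ UTR the 7-base word GAGAGGA, which is also in the ELOVL5 transcript and was chosen after a scan of all words (UBE2E3, FBXL16, COMMD8, EIF4EBP2, SMAP2 and ZNF618). The word is common, with 1667 carriers among 9050 scanned genes, so any single carrier named here or below may hold it by coincidence. Of all scanned words, 18.3% occur in ELOVL5 transcripts.

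In all, 26 genes were called after siELOVL5, 3 higher and 23 lower, and 5 falls and 0 rises were at least 2-fold; 1783 genes had an unadjusted p under 0.05. With replicate number as a block the count was 99, and these included all 26. A fit on the control and siELOVL5 libraries alone called only ELOVL5, and UBE2E3, LEPROTL1 and EIF4EBP2 then had an adjusted p of 0.0652 and FBXL16 of 0.0942. The count was 12, 9 and 9 without control replicate 1, 2 or 3, 15, 13 and 16 without siELOVL2 replicate 1, 2 or 3, 15 without siELOVL5 replicate 2 and 13 without double-knockdown replicate 2, and 145 with library weights. UBE2E3, FBXL16, LEPROTL1 and EIF4EBP2 stayed called without any 1 library. HSPA2 was lost without control replicate 1 (0.143), 2 (0.177) or 3 (0.0919), siELOVL2 replicate 1 (0.0546), 2 (0.0605) or 3 (0.0526), siELOVL5 replicate 2 (0.0548) or double-knockdown replicate 2 (0.0588). COMMD8 was lost without control replicate 1 (0.121), 2 (0.162) or 3 (0.0919), siELOVL2 replicate 2 (0.0558) or siELOVL5 replicate 2 (0.0991), FAM105A without control replicate 1 (0.0934), 2 (0.0965) or 3 (0.116) or siELOVL5 replicate 1 (0.0752), ZNF618 without control replicate 1 (0.0978), 2 (0.0965) or 3 (0.121), siELOVL2 replicate 2 (0.0508) or double-knockdown replicate 2 (0.0516), and SMAP2 without control replicate 2 (0.0938) or 3 (0.0919) or siELOVL5 replicate 2 (0.0548). Among the rises, CPA4 was lost without control replicate 1 (0.155), 2 (0.0965) or 3 (0.117), siELOVL2 replicate 1 (0.0516), siELOVL5 replicate 2 (0.0991) or 3 (0.0526) or double-knockdown replicate 2 (0.0516). SLCO2B1 was lost without control replicate 1 (0.244), 2 (0.0938) or 3 (0.193), siELOVL2 replicate 1 (0.0614), 2 (0.0762) or 3 (0.0651), siELOVL5 replicate 1 (0.133) or 2 (0.111) or double-knockdown replicate 1 (0.0715) or 2 (0.0684). RAPGEF2 was lost without control replicate 1 (0.197), 2 (0.22) or 3 (0.207), siELOVL2 replicate 1 (0.0814), 2 (0.0762) or 3 (0.0651), siELOVL5 replicate 1 (0.0952), 2 (0.111) or 3 (0.0676) or double-knockdown replicate 1 (0.0660) or 2 (0.0905).

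Interferon-stimulated genes were the list that stood highest after siELOVL5. All 38 measured members lay above control with a median of 0.79 (camera adjusted p = 4.44e-24, and 0.627 with an estimated correlation). Limma called 0 of them over all genes and 3 higher with the replicate block, 31 had an unadjusted p under 0.05, and 31 were higher when adjusted over the list alone. ISG15, a ubiquitin-like antiviral protein, was at 431, 252 and 531 normalized counts in siELOVL5 replicates 1, 2 and 3, against 213, 124 and 225 in the controls (1.09, adjusted p = 0.249, and 0.0393 with the block). MX1, an antiviral GTPase, was at 5124, 2314 and 5574 against 2538, 1049 and 2456. Without siELOVL5 replicate 3 the list kept a median of 0.61, with 38 of 38 members above control (camera adjusted p = 1.59e-15). Limma then called 0 of them. The members vary together (estimated correlation 0.689 with all libraries), and the stricter camera test was not run without that library.

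One library, siELOVL5 replicate 3, stood apart from all others, and several list results moved with it. Its deviations from the mean of its fellow replicates had an SD of 0.423 across genes at or above the median level, against 0.128 to 0.309 in the other libraries. In it the stress factor ATF3 reached 4390 normalized counts against 111 to 222 in the other 11 libraries, and the stress cytokine GDF15 reached 9053, the pro-apoptotic factor DDIT3 299, the cytokine IL6 1815 and the chemokine IL8 2853. TOP2A, the topoisomerase of dividing cells, was at 2351 and the mitotic kinase PLK1 at 431, the lowest of all libraries. With all libraries, ATF4 and amino acid response genes had a median of 0.42 with 31 of 31 above control (camera adjusted p = 1.67e-09) and immediate early genes 0.20 (0.00559). Mitosis and G2/M genes were at -0.40 (1.40e-09), mitochondrially encoded transcripts at -0.17 (0.0109), cholesterol genes at 0.14 (0.0475) and nuclear oxidative phosphorylation genes at -0.10 (0.00287). Without that library these medians were 0.06 (0.0673), -0.05 (0.895), -0.06 (0.271), 0.05 (0.508), -0.08 (0.166) and -0.02 (0.354), so that the directions of the immediate early, mitochondrial and cholesterol lists turned. NF-kappaB and inflammatory genes stood at 0.66 (3.01e-08), G1/S genes at -0.33 (6.47e-15) and histones at -0.40 (2.52e-11), and without it at 0.26 (0.00645), -0.13 (6.04e-07) and -0.16 (7.52e-05). The cholesterol call was also lost without control replicate 1 (0.536) or 2 (0.115) or double-knockdown replicate 1 (0.0577), 2 (0.0549) or 3 (0.0560), and with the stricter filter (0.0530), TMM scaling (0.0558), no trend (0.0879) or correction for length and GC content (0.0584). That correction also ended the mitochondrial call (0.232). With library weights the cholesterol (0.868), immediate early (0.679), oxidative phosphorylation (0.30) and mitochondrial (0.895) calls were lost. Without siELOVL5 replicate 3, hypoxia-inducible factor targets (-0.08, 0.00136) and the elongation and desaturation list (-0.13, 0.0166), which holds ELOVL5, passed as well. No list in this comparison passed with an estimated correlation (smallest adjusted p = 0.627). Of the members of these lists, limma called ELOVL5 and no other over all genes, and with the replicate block 1 ATF4 list gene higher and 1 NF-kappaB and 1 G1/S list gene lower. At an unadjusted p under 0.05 there were 20 G1/S, 15 histone, 11 NF-kappaB, 8 ATF4, 4 immediate early, 4 G2/M, 2 oxidative phosphorylation, 1 mitochondrial and 0 cholesterol genes.

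**Figure D2:**
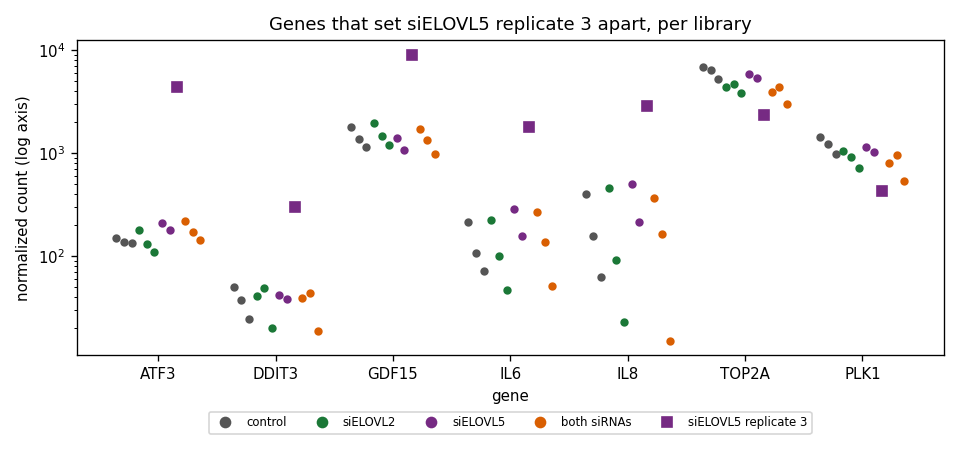
Normalized counts on a log axis of 5 stress and cytokine genes and of the cell cycle genes TOP2A and PLK1 in each of the 12 libraries, colored by siRNA, with siELOVL5 replicate 3 as a square. ATF3 is at 4390 in that library and at 222 or below in the other 11, and PLK1 is at 431 against 535 or above.

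The third comparison asks what lowering both elongases does. HMOX1 again had the largest rise, to 14510 ± 4571 normalized counts (SD, n = 3; log2 fold change 2.32, SE 0.21, limma adjusted p = 1.14e-04). ZNF469 rose by 1.21, the kinase gene PSKH1 by 1.20, SLCO2B1 by 0.96, the transporter gene SLC16A13 by 0.91 and CPA4 by 0.88. VBP1 fell from 610.4 ± 23.3 to 184 ± 32.0 (-1.74, limma adjusted p = 3.69e-05), CERK from 365 ± 28.4 to 118 ± 19.7 (-1.63, adjusted p = 1.15e-04) and CCNG1 from 686 ± 41.3 to 227 ± 11.5 (-1.59, adjusted p = 8.97e-06). HMGB3 fell by 1.71 on the log2 scale, ZNF367, a transcription factor gene, by 1.66, MOB1A, a Hippo pathway adaptor gene, by 1.52 and DPYSL3, a cytoskeletal regulator gene, by 1.51. VBP1, CERK, ZNF367, MOB1A and DPYSL3 carry ACGAATA and CCNG1 carries ACGATAA. These genes stayed called without any 1 library, and so did INSR, the insulin receptor (0.85), BCL2L11, a pro-apoptotic BCL2 relative (0.54), and STAT3 (0.55). HAS2, which makes hyaluronan, was called lower (-1.78) and PTGES, a prostaglandin E synthase, higher (1.42). HAS2 was lost without control replicate 1 (0.173), 2 (0.110) or 3 (0.0692), siELOVL2 replicate 2 (0.0689), siELOVL5 replicate 2 (0.0597) or double-knockdown replicate 1 (0.0769), 2 (0.0721) or 3 (0.128), and PTGES without double-knockdown replicate 2 (0.0547).

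In all, 825 genes were called after the double knockdown, 401 higher and 424 lower, and 39 of the rises and 77 of the falls were at least 2-fold. The share of rises was 48.6% and was 40.8% after TMM scaling. The count was 332, 325 and 492 without control replicate 1, 2 or 3, 387 and 343 without double-knockdown replicate 1 or 2, and 1775 without siELOVL5 replicate 3. It was 413 in limma without the trend, 1866 with the replicate block and 2241 with library weights.

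NRF2 and ferroptosis genes were also higher as a set after the double knockdown, with a median of 0.30 and 29 of 31 above control (camera adjusted p = 2.39e-10, and 0.0995 with an estimated correlation). Limma called 7 of them (14 without siELOVL5 replicate 3), and 16 when adjusted over the list alone. GCLM rose by 0.71 (adjusted p = 7.14e-04), GPX4 by 0.51 (0.00447) and NQO1 by 0.45 (0.00950), although NQO1 was lost without control replicate 2 (0.0630). Fatty acid oxidation and PPAR targets were at 0.15 (camera adjusted p = 0.0139, and 0.696 with an estimated correlation), lost without double-knockdown replicate 3 (0.165) and with library weights (0.0637). HADHB, of the mitochondrial trifunctional protein, rose by 0.54 (limma adjusted p = 0.00304). CPT1A, which admits fatty acids to mitochondria, was called at 0.52 (0.0185) and lost without control replicate 1 (0.0762) or 2 (0.0953) or double-knockdown replicate 1 (0.0542) or 3 (0.0596).

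Hypoxia-inducible factor targets were lower as a set, with a median of -0.38 and 24 of 31 below control (camera adjusted p = 2.60e-07, and 0.472 with an estimated correlation); 7 were called lower (11 without siELOVL5 replicate 3), and 12 when adjusted over the list alone. TGFA fell from 4232 ± 439.7 to 1899 ± 260.0 normalized counts (SD, n = 3; -1.16, limma adjusted p = 5.72e-04), EGLN1 by 0.74 on the log2 scale (1.96e-04), LDHA by 0.47 (0.00331) and HIF1A, the hypoxia-inducible subunit itself, by 0.39 (0.00772). EGLN1 carries ACGAATA and TGFA carries the common word GAGAGGA, and HIF1A was not called after correction for transcript length and GC content. EPAS1, which encodes another hypoxia-inducible subunit, was at -0.04 (limma adjusted p = 0.968) and the ubiquitin ligase gene VHL at 0.34 (0.240). Both were chosen after their values were seen. Whether the VHL protein acts on these subunits in A498 cells was not examined. Mesenchymal and matrix genes were at -0.17 with 23 of 34 below (camera adjusted p = 9.39e-05, and 0.0995 with an estimated correlation). Limma called 4 of them lower (10 without siELOVL5 replicate 3) and 12 when adjusted over the list alone, and CDH2 fell by 0.76 (1.77e-04).

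Cell cycle lists were lower as sets in the double knockdown too. Mitosis and G2/M genes had a median of -0.57 with 38 of 40 below control (camera adjusted p = 2.39e-10), histones -0.46 with 27 of 28 below (2.39e-10) and G1/S genes -0.35 with 34 of 40 below (1.16e-08), and each had 0.696 with an estimated correlation. Limma called 0 of the 40 G2/M genes, of which 21 had an unadjusted p under 0.05. It called 2 histone genes lower, and 15 when adjusted over the list alone. In the G1/S list CCNE1 rose by 0.57 (adjusted p = 0.00651), whereas the replication factors CDC45 (-0.66) and GINS2 (-0.47) were called lower; 16 G1/S genes were lower when adjusted over the list alone. Without siELOVL5 replicate 3, limma called 15 G2/M, 17 histone and 22 G1/S genes lower. With the replicate block and all libraries it called 30 G2/M, 16 histone and 10 G1/S genes lower. CDC45 was lost without control replicate 1 (0.0828) or 3 (0.0653) or double-knockdown replicate 1 (0.0752) or 3 (0.0555), and GINS2 without control replicate 2 (0.137) or 3 (0.117), siELOVL2 replicate 2 (0.0606), siELOVL5 replicate 2 (0.0509) or double-knockdown replicate 1 (0.129), 2 (0.0649) or 3 (0.0796). Nuclear oxidative phosphorylation genes were at 0.10 (camera adjusted p = 0.0151, and 0.835 with an estimated correlation), lost without control replicate 2 (0.0876) or double-knockdown replicate 3 (0.243). The p53 targets were at 0.18 (0.0361, and 0.835), lost without control replicate 3 (0.338) or double-knockdown replicate 1 (0.280), without the trend (0.0627) and with the stricter filter (0.0578).

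**Figure D3:**
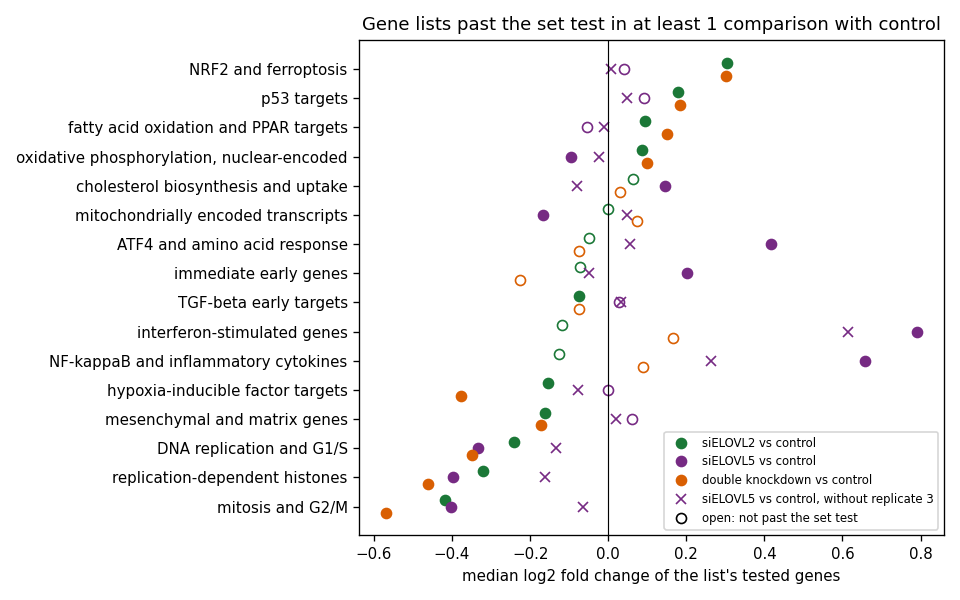
Median log2 fold change (horizontal axis) of the tested genes of the 16 lists that passed the camera test with its preset correlation in at least 1 knockdown against control; filled circles passed, open circles did not, and crosses give siELOVL5 without replicate 3. NRF2 and ferroptosis genes lie at 0.31 and 0.30 with siELOVL2 and with both siRNAs, and interferon-stimulated genes at 0.79 with siELOVL5 and 0.61 without its replicate 3.

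The differences between knockdowns show what each siRNA added to the other. Adding the ELOVL5 siRNA to the ELOVL2 siRNA lowered 11 genes and raised 0 (672 had an unadjusted p under 0.05). Apart from ELOVL5 (-3.50), they included COMMD8 (-1.17), UBE2E3 (-0.99), MIER1 (-0.82) and LEPROTL1 (-0.71). COMMD8 was lost without control replicate 1 (0.0519), siELOVL2 replicate 1 (0.153), 2 (0.107) or 3 (0.107) or double-knockdown replicate 1 (0.0609) or 2 (0.0633), and UBE2E3 without siELOVL2 replicate 1 (0.0551), 2 (0.0940) or 3 (0.0720) or double-knockdown replicate 1 (0.0609) or 2 (0.0847). MIER1 was lost without siELOVL2 replicate 1 (0.0539) or 3 (0.0642) or double-knockdown replicate 2 (0.0678), and LEPROTL1 without siELOVL2 replicate 3 (0.0642). COMMD8, UBE2E3 and MIER1 carry GAGAGGA, a word with 1667 carriers among 9050 scanned genes. The count was 7 without control replicate 1, 5, 5 and 2 without siELOVL2 replicate 1, 2 or 3, 6 and 3 without double-knockdown replicate 1 or 2, and 1 in a fit on these groups alone. It was 21 in limma without the trend and 27 with library weights. Interferon-stimulated genes were higher in this comparison, with a median of 0.31 and 36 of 38 above (camera adjusted p = 6.31e-07, and 0.926 with an estimated correlation), but not without double-knockdown replicate 1 (0.163). Hypoxia-inducible factor targets were at -0.12 (9.69e-05), G2/M genes at -0.14 (0.00914) and histones at -0.12 (0.0142), each with 0.926 under an estimated correlation. Without siELOVL5 replicate 3, a library outside this comparison, 3 more lists passed. They were G1/S genes (-0.08, camera adjusted p = 0.001655), mitochondrially encoded transcripts (0.10, 0.00484) and NF-kappaB genes (0.16, 0.0379). G2/M was lost without siELOVL2 replicate 1 (0.372) or 2 (0.181) or double-knockdown replicate 3 (0.638), and histones without siELOVL2 replicate 1 (0.163) or 2 (0.305) or double-knockdown replicate 1 (0.0812) or 3 (0.971) and without the trend (0.0584); library weights ended both calls (0.348 and 0.275).

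Adding the ELOVL2 siRNA to the ELOVL5 siRNA changed 516 genes, 253 higher and 263 lower. HMOX1 rose by 3.08, ZNF469 by 1.46, GALNT9, a glycosyltransferase gene, by 1.24, ERMP1 by 0.99 and SLC48A1 by 0.91. ELOVL2 fell by 3.17 on the log2 scale, DUSP3 by 1.68 and CERK by 1.61, and DUSP3 carries CACGATA and ACGATAA. The antiviral gene RSAD2 fell by 2.93 on the log2 scale but was lost without double-knockdown replicate 1, 2 or 3 (adjusted p = 0.0509, 0.0726 and 0.0706), without the trend (0.0773) and in a fit on these groups alone (0.223). It stood at 281.9, 174.4 and 1479 normalized counts in siELOVL5 replicates 1, 2 and 3, its log2 fold change without replicate 3 was -2.02 (0.00875), and it carries ACGAATA. The share of rises was 49.0% and was 37.2% after TMM scaling. The count was 324 without siELOVL2 replicate 2, 227 and 791 without siELOVL5 replicate 1 or 3, and 181, 154 and 303 without double-knockdown replicate 1, 2 or 3. It was 21 in a fit on these groups alone, in which ERMP1 (0.0558) was not called. The count was 200 without the trend, 1368 with the replicate block and 1251 with library weights.

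Compared directly, siELOVL5 and siELOVL2 cells differed in 562 genes, 272 higher and 290 lower in siELOVL5 cells. HMOX1 (log2 fold change -3.24), GALNT9 (-1.72), FBXL16 (-1.31) and ZNF469 were lower, while DUSP3 was 1.74 higher. RSAD2, which carries ACGAATA, was 3.22 higher (2.31 without siELOVL5 replicate 3), lost without siELOVL2 replicate 2 (adjusted p = 0.0705), without the trend (0.0593) and in a fit on these groups alone (0.164). The immune gene EPSTI1 (1.74) was called higher but lost without control replicate 1 (0.0587) or 3 (0.0518), siELOVL2 replicate 1 (0.0812), 2 (0.156) or 3 (0.134), siELOVL5 replicate 1 (0.102) or 3 (0.0947) or double-knockdown replicate 2 (0.0610). With replicate number as a block the count was 1317, and it included all 562. The share of rises was 48.4% and was 58.7% after TMM scaling. The count was 355 without control replicate 2, 270, 165 and 188 without siELOVL2 replicate 1, 2 or 3, 263 without siELOVL5 replicate 1 and 360 without double-knockdown replicate 2. It was 49 in a fit on these groups alone, 213 without the trend and 1643 with library weights.

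The interaction asks whether the double knockdown departed from the sum of the single ones on the log2 scale. Limma called 0 of 18648 genes (smallest adjusted p = 0.996), 522 had an unadjusted p under 0.05, and limma without the trend called 9. HMOX1, CCNG1 and DUSP3 were among the genes with no call. The test recovered 70.1% of simulated departures of 1 and 7.46% of those of 0.5 in 18648 genes, so departures of the smaller size were mostly below its reach. The median SE over the tested genes was 0.297, so departures of 1 can also be missed in genes with that SE or a larger one. At the level of lists, 14 of 31 passed with the preset correlation, 0 with an estimated one (smallest adjusted p = 0.570) and 1 without siELOVL5 replicate 3, the interferon-stimulated genes.

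Genes called after siELOVL2 moved the same way when the same siRNA was added to siELOVL5, a comparison that shares no library with the first. Of the 254, 252 had the same sign, the median ratio of fold changes was 0.967, and 73 rises and 120 falls were called in both, against 1.38 and 2.14 for independent lists. Across all genes, which are not independent replicates, the correlation was 0.325 (0.000625 simulated without effects; 0.743 over genes at or above the median level) and the covariance 0.0633 (8.30e-05 simulated). Genes called after siELOVL5 behaved likewise against double knockdown over siELOVL2. All 26 had the same sign, with a median ratio of 0.610, 8 falls and 0 rises were called in both (0.0136 and 0 for independent lists), and the correlation was 0.103 (0.525 over genes at or above the median level).

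Comparisons that share the control libraries correlate even with no effect. The fold changes of siELOVL2 and the double knockdown correlated at 0.687 (0.501 simulated) with a covariance of 0.139 (0.0664), and 93 rises and 141 falls were called in both (2.19 and 3.46 for independent lists). For siELOVL5 and the double knockdown the correlation was 0.476 (no higher than simulated) and the covariance 0.0907 (0.0662), with 2 rises and 16 falls in both (0.0645 and 0.523). For the 2 single knockdowns the correlation was 0.434 (0.501; 0.230 over genes at or above the median level) and the covariance 0.0758 (0.0663), with 1 rise and 2 falls in both (0.0164 and 0.188). With 3 controls no separate controls could be given to each comparison, so part of the excess can come from the shared controls. The simulated libraries had independent errors and the same spread for each gene. In the data siELOVL5 replicate 3 had a larger spread and same-numbered libraries varied together, so the simulated values are a rough guide.

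**Figure D4:**
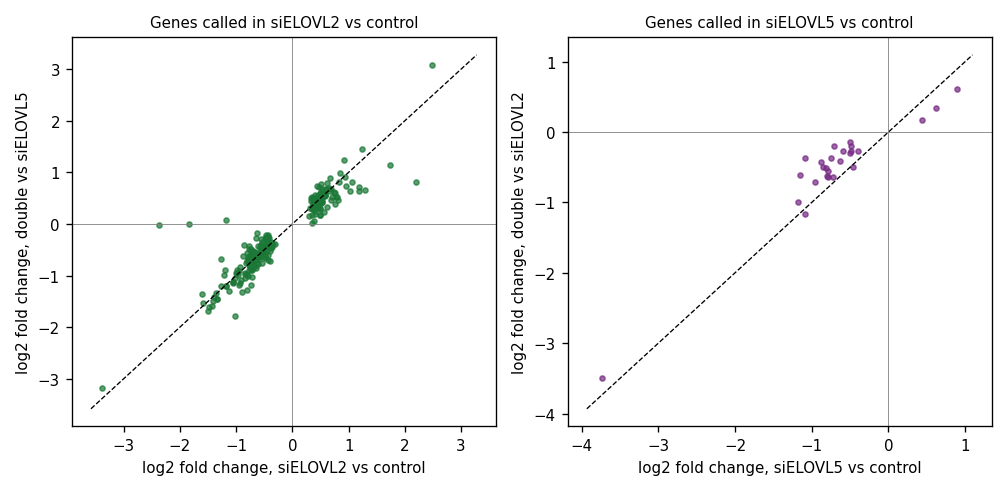
Log2 fold changes of the genes called after each siRNA against control (horizontal axis) and after the same siRNA was added to the other one (vertical axis), comparisons with no library in common; each point is a gene and the dashed line is equality. Of 254 genes called after siELOVL2 (left) 252 have the same sign on both axes, as do 26 of 26 after siELOVL5 (right).

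Among lipid lists, the fatty acid elongation and desaturation list, which includes both targets, did not pass against control. Its medians were 0.03, -0.11 and 0.04 after siELOVL2, siELOVL5 and both siRNAs (camera adjusted p = 0.703, 0.105 and 0.507). The desaturases FADS1 and FADS2, which act in the same pathway, had log2 fold changes of 0.30 and 0.17 after both siRNAs (limma adjusted p = 0.668 and 0.854), and the stearoyl-CoA desaturase SCD was at 0.09 (0.950). FADS3 (0.73) and ELOVL1 (0.35) were called higher after both siRNAs. FADS3 was lost without control replicate 1 (0.108), 2 (0.101) or 3 (0.0652) or double-knockdown replicate 1 (0.0702), 2 (0.0862) or 3 (0.0808), and ELOVL1 without control replicate 1 (0.147) or 2 (0.106), siELOVL2 replicate 2 (0.0552) or double-knockdown replicate 1 (0.121), 2 (0.0772) or 3 (0.0637). De novo fatty acid synthesis genes were at 0.06 and 0.11 after siELOVL5 and both siRNAs (camera adjusted p = 0.780 and 0.208), and cholesterol genes at 0.06 and 0.03 after siELOVL2 and both (0.670 and 0.881). Lipid droplet genes were at 0.11, 0.06 and 0.14 (0.648, 0.142 and 0.522), phospholipid remodelling genes at 0.04, -0.01 and -0.01 (0.882, 0.653 and 0.881), and eicosanoid synthesis genes at 0.00, -0.10 and 0.17 (0.789, 0.537 and 0.634). PTGS2, the inducible cyclooxygenase, had a log2 fold change of -1.78 after siELOVL2 (limma adjusted p = 0.107, and 0.0438 with the block) and carries ACGATAA.

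The remaining lists did not pass against control after siELOVL2, siELOVL5 or both siRNAs, in that order. The unfolded protein response list had medians of -0.01, -0.00 and -0.03 (camera adjusted p = 0.648, 0.653 and 0.460), STAT3 targets of -0.01, 0.09 and 0.07 (0.887, 0.153 and 0.837), and FOXO and PI3K-AKT feedback genes of -0.01, 0.10 and -0.05 (0.703, 0.196 and 0.837). STAT3 itself rose by 0.46 after siELOVL2 (limma adjusted p = 0.00184). Apoptosis regulators had medians of 0.03, 0.05 and 0.06 (0.703, 0.196 and 0.546), epithelial and proximal tubule markers of 0.00, -0.07 and -0.07 (0.393, 0.653 and 0.314) and ribosomal protein genes of 0.03, -0.04 and 0.03 (0.549, 0.105 and 0.577). RNA interference genes were at 0.11, 0.11 and 0.14 (camera adjusted p = 0.703, 0.271 and 0.577). However, DICER1, the nuclease that makes short RNAs, fell by 0.69 after both siRNAs (limma adjusted p = 0.00323) and carries the common word GAGAGGA. Leukocyte markers, 9 of 20 measured, were at 0.12, 0.00 and -0.27 (camera adjusted p = 0.648, 0.358 and 0.796), endothelial markers at -0.10, 0.12 and 0.00 (0.887, 0.367 and 0.987), and fibroblast markers at -0.29, 0.01 and -0.44 (0.266, 0.795 and 0.116).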

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

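The tests on interferon-stimulated genes, the test of an exchange of siELOVL5 replicate 3 with another group, library weights and the corrections for length and GC content were chosen after the result was seen, as was singling out the fits without that library; the tests of its depth and of RNA degradation were chosen before. Interferon-stimulated genes rose as a set after siELOVL5, with 38 of 38 above control (adjusted p = 0.627 with an estimated correlation), and had a median of 0.17 after both siRNAs (camera adjusted p = 0.246), so that the double knockdown lay below the sum of the single ones (interaction median -0.48, camera adjusted p = 2.51e-09). The interaction test found such a difference between knockdowns in 14 of 31 lists. The others were DNA replication and G1/S (0.26, 4.45e-09), ATF4 and amino acid response (-0.39, 2.45e-07), histones (0.29, 3.30e-05), mitochondrially encoded transcripts (0.28, 1.39e-04), immediate early genes (-0.33, 1.73e-04), NF-kappaB genes (-0.50, 1.73e-04) and mitosis and G2/M (0.24, 9.38e-04). Nuclear oxidative phosphorylation (0.10, 0.00311), p53 targets (-0.12, 0.00873), cholesterol genes (-0.26, 0.0139), hypoxia-inducible factor targets (-0.15, 0.0246), leukocyte markers (-0.55, 0.0351, 9 genes) and fatty acid oxidation (0.05, 0.0429) complete them. With an estimated correlation the smallest adjusted p was 0.570. Without siELOVL5 replicate 3 the interaction was past the threshold in 1 list, the interferon-stimulated genes (-0.25, 0.00602). Calls of lists in the interaction were also lost without other libraries. Cholesterol genes lost the call without control replicate 1 (0.346), siELOVL2 replicate 3 (0.303) or double-knockdown replicate 1 (0.162) or 2 (0.0887). Fatty acid oxidation lost the call without control replicate 3 (0.303), siELOVL2 replicate 1 (0.430) or 2 (0.0626), siELOVL5 replicate 1 (0.178) or double-knockdown replicate 3 (0.639). Hypoxia-inducible factor targets lost the call without control replicate 1 (0.0815), siELOVL2 replicate 2 (0.0626) or 3 (0.148) or double-knockdown replicate 1 (0.176) or 2 (0.450). NF-kappaB genes lost the call without double-knockdown replicate 3 (0.103). The p53 targets lost the call without control replicate 3 (0.303), siELOVL2 replicate 1 (0.199) or double-knockdown replicate 3 (0.147). Mitosis and G2/M lost the call without control replicate 1 (0.0570), siELOVL2 replicate 3 (0.155) or double-knockdown replicate 1 (0.0595) or 2 (0.257). Nuclear oxidative phosphorylation lost the call without double-knockdown replicate 3 (0.186). Histones lost the call without double-knockdown replicate 2 (0.0545). Leukocyte markers lost the call without control replicate 2 (0.105), siELOVL2 replicate 3 (0.111), siELOVL5 replicate 1 (0.162) or 2 (0.0624) or double-knockdown replicate 1 (0.102) or 3 (0.0741). Library weights ended 10 of the calls: NF-kappaB (0.709), fatty acid oxidation (0.536), oxidative phosphorylation (0.536), cholesterol (0.475), p53 (0.475), immediate early (0.475), mitochondrial (0.275), ATF4 (0.140), G2/M (0.140) and leukocyte (0.118). The replicate block ended the leukocyte and fatty acid oxidation calls (0.0812 each). Leukocyte markers were also lost with a pseudocount of 0.1 (0.0669) and the stricter filter (0.614), and with the block and length and GC content regressed out (0.0855). Fatty acid oxidation was also lost with no filter (0.0696), the stricter filter (0.127), TMM scaling (0.0565) and correction for length and GC content (0.0646, and 0.0935 with the block). Limma called 0 single genes in the interaction, 522 had an unadjusted p under 0.05, and limma without the trend called 9.

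Without siELOVL5 replicate 3 the interaction medians shrank to -0.09 for ATF4, 0.05 for G1/S, 0.02 for histones, 0.02 for mitochondrial, -0.11 for immediate early and -0.11 for NF-kappaB genes. They were 0.02 for oxidative phosphorylation, -0.06 for p53 targets and -0.01 for hypoxia-inducible factor targets, and G2/M (-0.10) and cholesterol genes (0.04) turned direction. Leukocyte markers were then at -0.51 and fatty acid oxidation at 0.06, close to their medians with all libraries, but both calls were lost (0.110 each). In siELOVL5 replicate 3 stress genes such as ATF3 (4390 normalized counts, against 222 or less elsewhere) stood high and cell cycle genes such as PLK1 (431) low. Lower depth is argued against, since shallower libraries had deviations with at most 0.530 of its SD. Its own depth is uncertain, at 1.062 and 0.8475 reads per unit of normalized value at 10 and 100 reads. Control replicate 1 (0.8163 and 0.7989) and double-knockdown replicate 1 (0.7947 and 0.8) were lower at both. Degraded RNA would give low values to long transcripts, whereas the deviation had a Spearman correlation of 0.11 with length. An exchange with a library of another group is argued against by the targets: ELOVL5 stood at 155.6, against 1791 or above without its siRNA, and ELOVL2 at 164.6, against 30.1 or below with its own, a ratio of 5.47. A stressed culture, a difference in handling or an outside sample given the same siRNA stays open and was not tested.

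The rise of interferon-stimulated genes after siELOVL5 did not rest on that library alone. Without it the median was 0.61 with 38 of 38 genes above control, although limma called 0 of them. The members vary together (estimated correlation 0.689 with all libraries), so they are not 38 independent observations. In siELOVL5 replicate 2, MX1 (2314) lay within the control range (1049 to 2538), while ISG15 (252) lay above its own (124 to 225). Same-numbered libraries varied together, and control replicate 2 was the lowest control for both genes. Against the control of the same number, MX1 was higher in siELOVL5 replicate 1 (5124 and 2538), 2 (2314 and 1049) and 3 (5574 and 2456). The rise may be a response to lower ELOVL5 or to the siRNA duplex itself. Against siELOVL2, the double knockdown had a median of 0.31 with 36 of 38 above, as either needs, but not past the threshold without double-knockdown replicate 1 (0.163) or with an estimated correlation (0.926). The rise was smaller there by the interaction with the preset correlation, and not past the threshold with an estimated one (0.570). These explanations cannot be told apart, because each gene was lowered under 1 label, and neither the number of siRNAs per gene nor the amount of each in the double knockdown is given in the sources used here.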

How the results depend on the processing

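Library weights, the corrections for transcript length and GC content, the fits without siELOVL5 replicate 3 as a chosen setting and the comparisons that share no library were chosen after the data were seen; the other settings were planned. The fold changes of ELOVL2 and ELOVL5 after their own siRNAs, alone or together, kept their direction and their side of the threshold in all 23 alternatives. ELOVL2 ranged from -3.55 to -3.18 after siELOVL2 and ELOVL5 from -3.77 to -3.70 after siELOVL5. Of 137 pairs of named gene and comparison, 64 kept their call in every setting and 73 lost it in at least 1, and 0 reversed. With the replicate block and all libraries, all 137 kept their call. The fits without 1 library had no block. A pseudocount of 0.1, other filters, quantile normalization, TMM scaling and regression on length and GC content left the total of called genes in each comparison within 1.5 times. The rises after siELOVL5 moved further, from 3 to 5 with no filter and to 1 with length and GC content regressed out.

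Counts of called genes moved under other settings, and the cause was not tested. Without the intensity trend limma called 101 genes after siELOVL2, 413 after both siRNAs, 21 in double knockdown against siELOVL2, 200 in double knockdown against siELOVL5, 213 in siELOVL5 against siELOVL2 and 9 in the interaction. With the replicate block it called 861 after siELOVL2, 99 after siELOVL5 and 1866 after both, 1368 in double knockdown against siELOVL5 and 1317 in siELOVL5 against siELOVL2. With the block and length and GC content regressed out, these 5 counts were 770, 55, 1640, 1215 and 1191. After both siRNAs the block alone called 30 G2/M, 16 histone and 10 G1/S genes lower. With library weights, which gave siELOVL5 replicate 3 a weight of 0.228, the counts were 1569 after siELOVL2, 145 after siELOVL5 and 2241 after both. They were 27 in double knockdown against siELOVL2, 1251 in double knockdown against siELOVL5 and 1643 in siELOVL5 against siELOVL2. In fits on the compared groups alone, which have fewer residual degrees of freedom, the counts were 412 after siELOVL2, 1 after siELOVL5, 1 in double knockdown against siELOVL2, 21 against siELOVL5 and 49 in siELOVL5 against siELOVL2.

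Leaving out each library in turn gave 63 to 829 genes after siELOVL2, 9 to 39 after siELOVL5, 325 to 1775 after both, 2 to 16 in double knockdown against siELOVL2, 154 to 791 against siELOVL5 and 165 to 707 in siELOVL5 against siELOVL2. The interaction stayed at 0. Lists past the threshold numbered 6 to 13 after siELOVL5 and 1 to 13 in the interaction. With an estimated correlation, 0 lists passed after siELOVL2, siELOVL5 or both and 0 in the interaction, where library weights gave 4; with the block NRF2 and ferroptosis genes passed after siELOVL2 (0.0435). Beyond the calls given with the results, the block changed no list call against control except de novo fatty acid synthesis after both siRNAs. That list had a camera adjusted p of 0.0190 with the block, and 0.368 with the block and an estimated correlation.

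Over genes at or above the median level, correlations of fold changes were 0.230 for the 2 single knockdowns, 0.892 for siELOVL2 and the double knockdown, 0.743 for siELOVL2 and double knockdown against siELOVL5, and 0.525 for siELOVL5 and double knockdown against siELOVL2. Without 1 library they were, over all genes, 0.373 to 0.550 for the single knockdowns, 0.617 to 0.748 for siELOVL2 and the double knockdown, and 0.418 to 0.574 for siELOVL5 and the double knockdown. With no shared library they were 0.272 to 0.341 for siELOVL2 and 0.0710 to 0.114 for siELOVL5. Depth limited genes whose normalized count lay under 0.917, which can stand for no read. The planned count-based test on recovered reads was not run, since reads were recovered for low counts only.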

Other observations

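The tests of seed words against transcript length and GC content and against other comparisons were written before their results were seen; the set of 3 leading words, the shares without the targets, the splits within replicate number, and the genes RXRA, CENPB, TMEM127, ELAVL1 and BACH1, were chosen after. RXRA, the retinoid X receptor that pairs with PPAR and other lipid sensors, fell by 0.75 on the log2 scale after siELOVL5 (limma adjusted p = 0.00110). It was called without any 1 library (up to 0.0119), and after both siRNAs it was at -0.32 (0.0362, up to 0.137 without 1 library). The 3′ UTR scanned for it, of 408 bases, carries none of the leading words, and a longer form was not scanned. CENPB, a centromere protein, was at 669.8 normalized counts in control cells, 429.5 after siELOVL2, 488 after siELOVL5 and 302.9 after both, with log2 fold changes of -0.64 (0.00123), -0.46 (0.0411, up to 0.259 without 1 library) and -1.14 (8.97e-06). TMEM127, an endosomal membrane protein, fell by 1.13 after siELOVL2 (7.98e-05), and the RNA-binding protein ELAVL1 by 0.99 (7.36e-04). The 3′ UTR of TMEM127 carries ACGAATA, and that of ELAVL1 carries CACGATA and ACGATAA, words that mark falls after siELOVL2.

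Falls after the ELOVL2 siRNA may include transcripts silenced through the siRNA's seed, the bases that pair with 3′ UTRs. Of all scanned words, 20.2% occur in ELOVL2 transcripts. Among these, carriers of CACGATA had the clearest fall in the scan (126 genes, mean difference -0.21 adjusted for UTR length and GC content, Bonferroni-adjusted p = 2.89e-20). They were also lower in double knockdown against siELOVL5, which shares no library (-0.24, 6.43e-20), but not after siELOVL5 (0.01, 1). Of 137 falls with a 3′ UTR and a level at or above the median, 21 carried CACGATA (15.3%, exact 95% interval 9.75 to 22.5, and 20 of 136 without ELOVL2 itself). At such levels 1.19% of uncalled genes and 0 of 92 rises carried it, so this word alone does not account for most of these falls. At least 1 of the 3 leading words was in 57 of the 137 falls (41.6%), 3.76% of uncalled genes and 0 of the 92 rises. These words were chosen on the same fold changes, which raises such shares, so the comparison that shares no library is the stronger test. The word with the strongest fall, ACGAATA, is not in the ELOVL2 transcript (165 genes, -0.23, 1.26e-34), and the siRNA sequence is not given in the sources used here. A trend with length or GC content is argued against, since 80.9% of falls stayed called after correction.

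The falls after the ELOVL5 siRNA had the same kind of mark. Carriers of GAGAGGA, in the ELOVL5 transcript, were lower by a small amount (1667 genes, -0.05, Bonferroni-adjusted p = 2.16e-13), and also in double knockdown against siELOVL2 (-0.04, 2.71e-23) but not after siELOVL2 (-0.01, 1). Of the 22 falls other than ELOVL5, 15 carried it (68.2%, exact 95% interval 45.1 to 86.1), against 18.3% of uncalled genes; this word too was chosen on these fold changes. For carriers of these words such as UBE2E3, CCNG1, EGLN1 and CDH2, loss of the elongase and silencing through the seed are therefore both candidate explanations. Rises such as HMOX1 could follow from either, as BACH1, its repressor, carries CACGATA and was at -0.68 (limma adjusted p = 0.178, and 0.0337 with the block). An siRNA of other sequence for each gene would be needed to separate them.

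Other splits of the libraries were counted for each comparison. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes each time. The real and highest other counts were 254 and 0 after siELOVL2, 26 and 1 after siELOVL5, 825 and 0 after both, 11 and 0 in double knockdown against siELOVL2, 516 and 2 against siELOVL5, and 562 and 0 in siELOVL5 against siELOVL2. For a test of any difference among the 4 groups, 1 of 100 splits gave as many as the real 836 genes (highest other 25), a share under 0.05. The number of splits limits how small this share can be, so chance is less likely but not excluded. Those splits ignored replicate number; with groups exchanged only among libraries of the same number, 1 of 100 again gave as many, and the highest other count was 577. For the interaction the real count is 0, which all 100 of 100 splits reach by necessity, so the share tests nothing. The highest other count, 1864, points to structure among the samples, which can be the knockdown effects themselves, and its cause was not tested.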
